A study of Mus musculus with 2 samples.

How the data were processed

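Each genotype had 1 library, made per the labels from F4/80+ cells sorted by flow cytometry from peritoneal lavage, with the 10x Genomics Single Cell 3' v3 chemistry, on an Illumina NovaSeq, at a minimum of 20000 reads per cell. The counts were UMI counts per gene and barcode as deposited, made by the authors with Cell Ranger 6.1.2 per the file headers and holding called cells only. The submitters' processing notes also list bcl2fastq and Seurat 4.1.0 without saying what they did to these files. The notes name the mm9 assembly, but all 55450 feature identifiers are in GENCODE release 21 of the mouse annotation (55536 genes, GRCm38), which was used here for gene positions. Reads were not used here. Of the features, 25984 had a UMI in at least 1 barcode, and 109 features repeat a symbol of another feature. The symbols Ear11, Ero1a, Stimate and Sting1 were not found.

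Barcodes with under 500 genes or over 10% mitochondrial UMIs were left out. Scrublet was run on each library. Its automatic thresholds called 3 and 5 barcodes, 0.0472% and 0.0799%, below the 0.5% taken as the least for a working threshold. The barcodes with the highest scores were therefore removed at the rate of 0.8% per 1000 barcodes, 324 in the knockout (5.09%) and 313 in the wild type library (5.00%). Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were taken, and cells were clustered by the Leiden method at resolution 1 on a shared-neighbour graph of 15 neighbours, without integration of the libraries. Clusters were named from fixed marker lists of 16 classes. A marker counted if it was at least 2-fold above the other cells of the same library and seen in at least 10% of cells, with at least 3 markers needed. A cluster without such a class was named large-macrophage-like if at least 3 of that class's markers were seen in at least 25% of its cells. At least 20 cells of a library were needed, and the 10 leading genes of each cluster were checked. The thresholds for counting markers were set once the data were in hand. No cluster was left unnamed.

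UMIs of each class were summed per library, which is the sum over the cells of 1 library and no replicate, and scaled to CPM. Ratios are log2 of knockout over wild type CPM with 1 added to each, with exact conditional binomial intervals for counting error. Genes at 20 CPM or more in the higher library were counted at 2-fold. Named genes had at least 50 CPM and were the 12 with the highest and the 12 with the lowest log2 ratio in large-macrophage-like cells, and 5 of each in other classes, leaving out Ankrd22, mitochondrial, ribosomal, immunoglobulin, sex-linked and haemoglobin genes and unnamed gene models. For each of 40 gene lists fixed beforehand, members with a mean of at least 5 CPM were measured, the 4 members with the largest absolute log2 ratio and a mean of at least 20 CPM were open to naming, and the median was set beside 10000 random lists matched in 20 expression bins. Shares of cells with a UMI were taken after thinning each cell to 2000 UMIs. The random seed was 0.

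A planted-difference trial drew counts per gene from the pooled profile of all cells kept, at the UMI totals of the knockout and wild type libraries. Of 4790 genes, 200 were altered, 50 at each fold size. At 1.5-fold 0 of 50 passed the 2-fold rule, at 3-fold 50 of 50, at 4-fold 50 of 50 and at 8-fold 50 of 50, and 0 of 4590 unaltered genes passed. Of the 4790 intervals, 95.2% held the true value. The trial used counting noise only, at the depth of whole libraries and not of single classes, and its intervals had no 1 added to CPM.

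Tools were Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16.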

Results

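The data set held 2 single-cell RNA libraries of F4/80+ cells sorted from the peritoneal lavage fluid of mice, 1 from Ankrd22 knockout animals made with CRISPR/Cas9 and 1 from wild type animals. F4/80 is the surface antigen encoded by Adgre1 and marks macrophages. Ankrd22 encodes an ankyrin repeat protein, and the comparison asked how peritoneal macrophages lacking it differ in their transcripts from those of wild type mice. The knockout library held 6706 barcodes with 110956482 unique molecular identifiers (UMIs), and the wild type library 6315 barcodes with 96869041 UMIs, where 8000 cells had been expected per capture. The median was 15790.5 UMIs and 3490 genes per barcode in the knockout library, and 14569 UMIs and 3094 genes in the wild type library. After cell filters and doublet removal, 6036 knockout and 5946 wild type cells were kept, with medians of 16005.5 and 14339 UMIs. With 1 library per genotype there was no replicate check, so every difference below is between these libraries, and no test was made. Intervals of shares and of single genes cover counting error only. Intervals of list medians cover the spread between the members of a list, taken as independent. No interval covers variation between animals or libraries.

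The targeted gene was not seen in either library. Ankrd22 (ENSMUSG00000024774, chromosome 19, 34121469 to 34166053 on the minus strand, GRCm38) had 0 UMIs in the knockout and 0 UMIs in the wild type library over all barcodes. A count of 0 allows up to 0.0270 CPM, the UMIs of a gene scaled to the same total, in the knockout and 0.0310 CPM in the wild type library at 3 counts. In cells, the same 3 counts make 0 of 6706 allow a share with a UMI of up to 0.0447%, and 0 of 6315 one of up to 0.0475%. Ankrd22 was therefore not detectable at this depth even in wild type cells, and it does not check the genotype labels. The labels do not say which part of the gene was deleted. Of its chromosomal neighbours, 6 of 25 listed genes were measured in the main macrophage class, with a median log2 ratio of 0.09 (95% interval -0.42 to 0.50), a value that lay below 0 under both other scalings. Among them the death receptor gene Fas was at 36.5 and 49.2 CPM, and the lysosomal lipase gene Lipa at 141 and 99.2 CPM in the knockout and the wild type library.

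Large peritoneal macrophages, the resident GATA6-dependent population, made up most of both sorts. Large-macrophage-like cells were 5081 of 6036 knockout cells (84.2%, exact binomial 95% interval 83.2 to 85.1%) and 4514 of 5946 wild type cells (75.9%, 74.8 to 77.0%). Small-macrophage-like cells, with MHC class II genes, Retnla and Ccr2 among their markers, were 444 cells (7.36%, 6.71 to 8.04%) and 1047 cells (17.6%, 16.6 to 18.6%). Cells with cell cycle markers were 472 (7.82%, 7.15 to 8.53%) and 346 (5.82%, 5.24 to 6.44%), and 39 B-cell-like barcodes were found in each library (0.646% and 0.656%). The libraries were almost separate: 12 of 14 clusters, with 11584 of 11982 cells, were at least 95% of 1 library. Large-macrophage-like cells came almost all from clusters 2, 3, 4, 9 and 10 in the knockout and from clusters 0, 1 and 11 in the wild type library, and small-macrophage-like cells from cluster 6 and cluster 5. Genes that name the small macrophage class differed within it in both directions, with Ccr2 at 193 and 34.7 CPM and Folr2 at 50.4 and 109 CPM. No order is therefore read from these shares, which the F4/80 gate can also set. Across 10 other settings, the share of small-macrophage-like cells ran from 6.11 to 9.63% in the knockout and from 6.46 to 25.2% in the wild type library. The large-macrophage-like share ran from 64.4 to 89.3% and from 42.2 to 86.2%, and it was higher in the knockout library in 6 of the 10 settings.

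**Figure D1:**
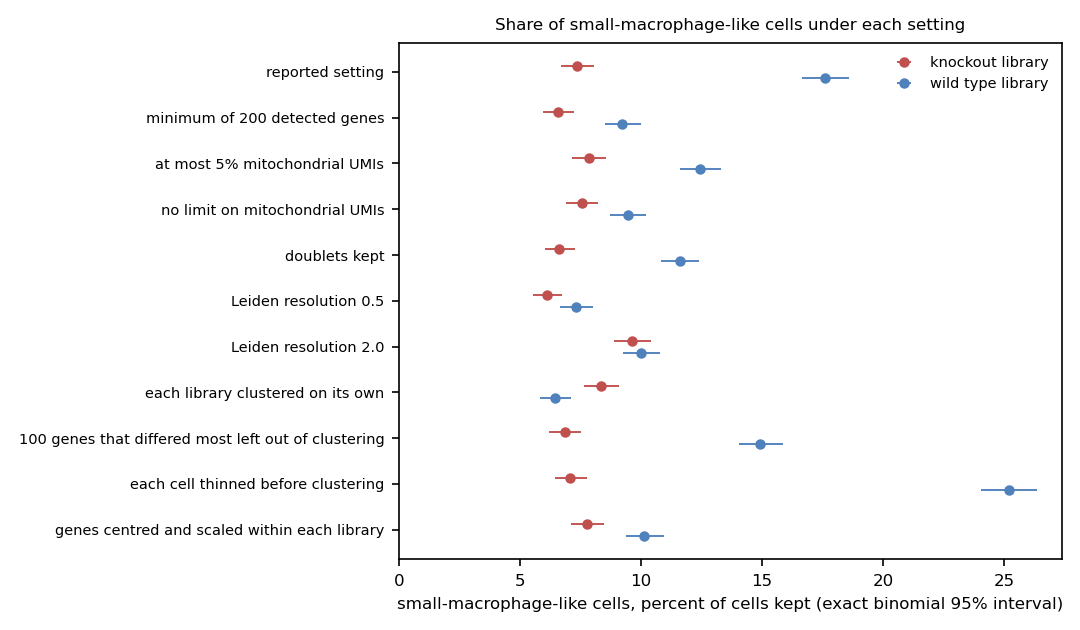
Share of small-macrophage-like cells among the cells kept (x axis, percent, with exact binomial 95% intervals for counting error) in the knockout and the wild type library under the reported setting and 10 others (y axis). The wild type value runs from 6.46 to 25.2% and the knockout value from 6.11 to 9.63%, and the wild type share is the higher one in 9 of the 10 other settings.

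Large-macrophage-like cells of the knockout library held far more Spp1 and Chil3 and far less Cxcl2 and Tnfaip3 transcript than those of the wild type library. Spp1 (ENSMUSG00000029304), which encodes the secreted phosphoprotein osteopontin, was at 632 CPM in the knockout and 6.77 CPM in the wild type library, a log2 ratio of 6.35 (counting interval 6.23 to 6.47). Chil3 (ENSMUSG00000040809), which encodes a secreted chitinase-like protein, was at 350 and 12.4 CPM, a log2 ratio of 4.71 (4.62 to 4.81). Cxcl2 (ENSMUSG00000058427), a chemoattractant of neutrophils, was at 374 and 8073 CPM, a log2 ratio of -4.43 (-4.44 to -4.41). Tnfaip3 (ENSMUSG00000019850), which encodes an inhibitor of NF-kB signalling, was at 4.70 and 130 CPM, a log2 ratio of -4.52 (-4.64 to -4.40).

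The other 10 named genes on the higher side had log2 ratios from 1.38 to 1.95. They were Arg1 (arginase, 204 and 56.7 CPM, log2 ratio 1.83), the carbonic anhydrase gene Car6 (1.93), the small GTPase gene Rhoc (346 and 90.9 CPM, 1.92), Lrg1 (1.38) and the calcium-binding protein gene S100a6 (2406 and 794 CPM, 1.60). The nuclear noncoding RNAs Kcnq1ot1 (1.95), Neat1 (1.69) and Malat1 (12606 and 4857 CPM, 1.38) were higher as well, as were Rsrp1 (1.76) and Vmn2r26 (1.48). Vmn2r26 belongs to a large receptor family and Chil3 has close paralogs, so their counts are uncertain where reads could be shared. On the lower side stood Cxcl1 (39.5 and 570 CPM, log2 ratio -3.82), the atypical chemokine receptor gene Ccrl2 (-4.04) and Rgs1, a regulator of G protein signalling (205 and 1652 CPM, -3.01). Cxcl13, a B cell chemoattractant and 1 of the markers that name the class, had a log2 ratio of -2.71. The cyclic AMP phosphodiesterase gene Pde4b (-2.53), the kinase gene Sgk1 (-2.39), the transcription factor genes Nfil3 (-2.39) and Atf3 (-2.24), the NF-kB cofactor gene Nfkbiz (-2.27) and the growth factor gene Igf1 (-2.26) followed. Of 5010 genes at 20 CPM or more in the higher library, 92 were at least 2-fold higher and 96 at least 2-fold lower in the knockout library, so 48.9% of them were higher. The median gene lay at a log2 ratio of 0.21. Scaling by TMM factors shifted all ratios by -0.29 and gave 42 higher and 162 lower genes (20.6% higher), and scaling by median of ratios shifted them by -0.28 and gave 42 and 160 (20.8% higher). The 24 genes named here kept their direction under both. Shifts of that size could not reverse ratios this far from 0, so this is no check of these genes.

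**Figure D2:**
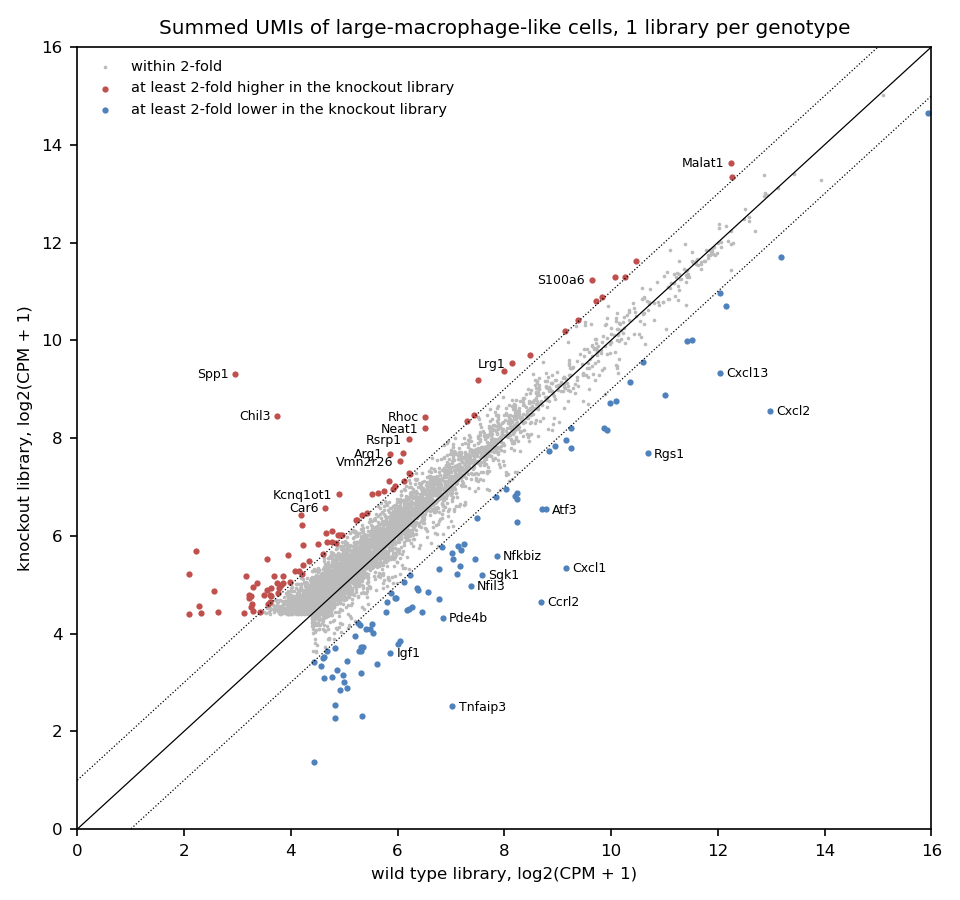
Each point is a gene at 20 CPM or more in the higher library, with UMIs summed over large-macrophage-like cells, as log2(CPM + 1) in the wild type (x axis) and the knockout library (y axis). Red marks the 92 genes at least 2-fold higher and blue the 96 at least 2-fold lower in the knockout library (42 and 162 under TMM scaling), and dotted lines mark 2-fold; Spp1 at 632 and 6.77 CPM and Cxcl2 at 374 and 8073 CPM lie far from the diagonal.

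In single large-macrophage-like cells thinned to 2000 UMIs, Spp1 was seen in 28.4% of knockout and 0.583% of wild type cells (51.4% and 1.93% unthinned). Cxcl2 was seen in 25.5% and 95.6% (54.6% and 99.6% unthinned), Chil3 in 27.3% and 1.95% (63.8% and 9.74% unthinned), and Tnfaip3 in 1.05% and 20.5% (5.73% and 64.4% unthinned). Thinning left out 37 knockout and 56 wild type cells below that depth, and the median depths were 15299 and 13989.5 UMIs. In B-cell-like barcodes, which should lack Spp1 and Chil3, thinned shares were 0 of 33 and 0 of 37 for Spp1 (allowing up to 9.09% and 8.11% at 3 counts), and 3 of 33 (9.09%) and 0 of 37 for Chil3. For Cxcl2 they were 9.09% in the knockout and 40.5% in the wild type library, and for Tnfaip3 6.06% and 16.2%, at median depths of 4417 and 5057 UMIs. Unthinned, these barcodes held Spp1 in 12.1% and 0%, Chil3 in 15.2% and 0%, Cxcl2 in 9.09% and 86.5%, and Tnfaip3 in 12.1% and 29.7%. B cells can express Tnfaip3 themselves, so its share there is no measure of free RNA.

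Inflammatory and early-response genes were lower in the knockout library as groups, under all scalings. Of 20 measured inflammatory cytokine and chemokine genes, 15 were at least 1.5-fold lower and 0 at least 1.5-fold higher, with a median log2 ratio of -1.68 (order-statistic 95% interval -2.55 to -1.08), lower than all 10000 random lists matched on expression. Besides Cxcl2 and Cxcl1, the prostaglandin synthase gene Ptgs2 (3.97 and 39.3 CPM, log2 ratio -3.02) was among the lowest. Of 21 immediate early genes, which respond within minutes to stimulation or handling, 10 were at least 1.5-fold lower and 0 higher, with a median of -0.54 (-1.28 to -0.08). Examples were Atf3 (92.1 and 438 CPM), Fosb (-2.02), Klf6 (-1.44) and the phosphatase gene Dusp1 (-1.43). Among 20 NF-kB targets and regulators 8 were at least 1.5-fold lower and 0 higher (median -0.23, -1.05 to -0.01), with Nfkbiz at 47.2 and 232 CPM, Nfkbia at -1.33 and Ier3 at -1.18. Pattern recognition receptors (19 measured, median -0.14, -0.78 to 0.19) had 7 members at least 1.5-fold lower and 1 higher, with Tlr2 at -1.39 and Cd14 at -1.21. Unfolded protein response genes had a median of -0.31 (19 measured, -0.62 to -0.03), 5 at least 1.5-fold lower, with Ppp1r15a at -1.47 and the chaperone gene Hspa5 at -0.62. Heat shock proteins had a median of -0.15 (15 measured, -0.44 to 0.03), with Hsph1 at -1.06 and Hspa4 at 0.66. NFAT targets and calcineurin genes had one of -0.15 (12 measured, -0.92 to 0.10), with Nr4a1 at -1.38. The intervals of the pattern recognition, heat shock and NFAT lists cross 0.

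Of 16 complement genes 6 were at least 1.5-fold lower and 0 higher, and 5 lay above 0 (median -0.25, -0.72 to 0.09, an interval that crosses 0). The lowest included the chains of C1q: C1qa at 1664 and 4547 CPM (log2 ratio -1.45), C1qc at -1.07 and C1qb at -0.81. The median of 8 measured MHC class II presentation genes was -0.50 (-0.85 to 0.21) and that of 15 MHC class I genes -0.01, where B2m was at -0.40 and Tapbp at -0.53. The 4 class II genes that are not markers of the small macrophage class had a median of -0.17, with 2 above 0. Interferon gamma response genes had a median of 0.59 (10 measured, -0.44 to 0.94), with 5 at least 1.5-fold higher, among them the guanylate-binding protein genes Gbp2 (1.10) and Gbp3 (0.90), and 1 lower, Irf8 (-0.74). Type I interferon response genes had a median of 0.28 (24 measured, 0.05 to 0.43), with Parp14 at 1.13 and Ifi27l2a at -0.55, and lay inside the range of its random lists, near the median gene. Both interferon medians stayed above 0 under the other scalings.

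All 13 mitochondrially encoded transcripts were at least 1.5-fold higher in the knockout library. Their median log2 ratio was 1.03 (0.78 to 1.30), above all 10000 matched random lists, with mt-Atp8 at 206 and 67.6 CPM and mt-Nd5 at 657 and 253 CPM. In the same cells the median mitochondrial share per cell was 1.49% in the knockout and 0.697% in the wild type library. Nuclear-encoded oxidative phosphorylation genes stood near the median gene at 0.20 (71 measured, 0.13 to 0.25, 0 at least 1.5-fold apart), below 0 under TMM (-0.09) and median of ratios (-0.09). Fatty acid oxidation genes had a median of 0.40 (20 measured, 0.23 to 0.50), against 0.21 for the median gene, which stayed above 0 under both other scalings for this list. Of them 19 of 20 lay above 0, but only 3 were at least 1.5-fold higher. The dehydrogenase gene Acadl (141 and 73.0 CPM, log2 ratio 0.94) and Acaa2 (0.81) were the highest. Genes of calcium entry, stores and mitochondrial calcium had a median of 0.29 (31 measured, 0.13 to 0.42), near the median gene, inside the range of its random lists and at 0.00388 under TMM, with the calmodulin gene Calm2 (0.83) and the store sensor and channel genes Stim1 (0.74) and Orai1 (0.67) among 6 that were at least 1.5-fold higher. The tricarboxylic acid cycle list (24 measured) and glycolysis list (18 measured) had medians of 0.23 and 0.24, autophagy 0.21 (20 measured) and cholesterol synthesis 0.23 (13 measured), all near the median gene and all below 0 under TMM and median of ratios.

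**Figure D3:**
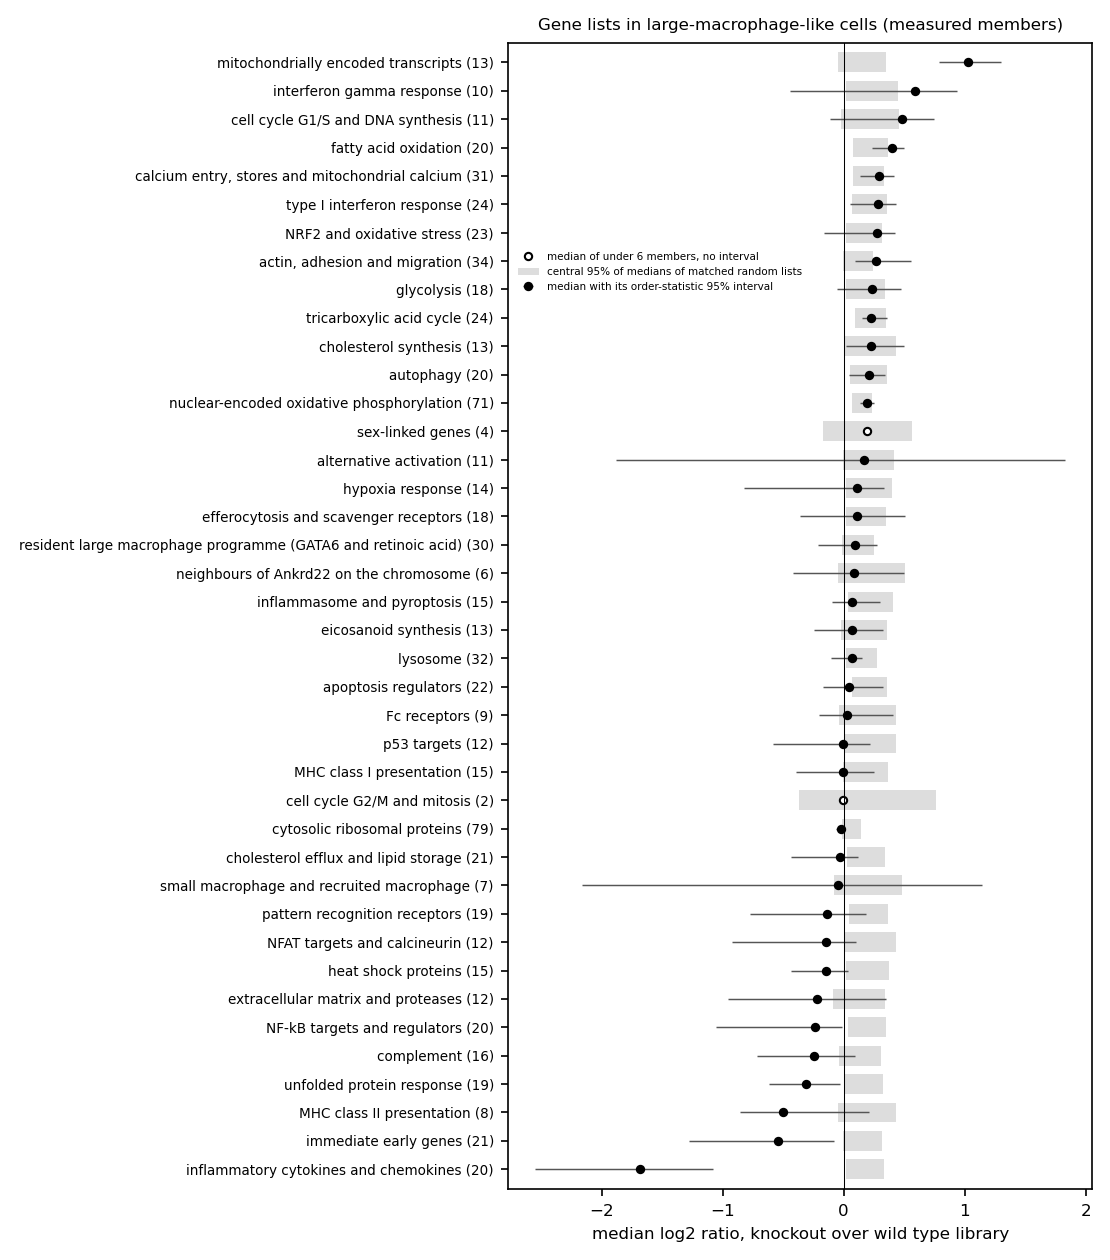
Median log2 ratio, knockout over wild type library, of each of 40 gene lists in large-macrophage-like cells (x axis), with order-statistic 95% intervals; grey bars hold the central 95% of the medians of 10000 random lists matched on expression, and the number of measured members stands beside each list (y axis). Mitochondrially encoded transcripts lie at 1.03 and inflammatory cytokines and chemokines at -1.68, and under TMM scaling, which shifts all values by -0.29, 6 instead of 24 medians lie above 0.

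Genes of macrophage identity showed members on both sides. The resident large macrophage programme had a median of 0.10 (30 measured, -0.21 to 0.27; below 0 under TMM and median of ratios), with 5 members at least 1.5-fold higher and 6 lower. Its transcription factor gene Gata6 was at 177 and 162 CPM, Icam2 at 1333 and 726 CPM, and the matrix protein gene Thbs1 at 1033 and 2920 CPM. The lysozyme gene Lyz2 took 2.59% of the UMIs of knockout and 6.24% of those of wild type cells (log2 ratio -1.27). Alternative activation genes went both ways (11 measured, median 0.17, -1.88 to 1.83): Chil3 and Arg1 were higher and Retnla (92.4 and 417 CPM, -2.16) and F13a1 (-1.88) lower. Actin, adhesion and migration genes had a median of 0.26 (34 measured, 0.09 to 0.56; below 0 under TMM and median of ratios), with 10 at least 1.5-fold higher, S100a6, Coro1a (1.16) and S100a4 (1.05) among them, and 2 lower, Lgals1 at -1.79 the lowest. Matrix and protease genes had a median of -0.22 (12 measured), with Spp1 at 6.35 and the matrix protein gene Tgfbi at -1.47. Genes of cholesterol efflux and lipid storage had a median of -0.03 (21 measured), with Hilpda at -1.73 and Apoe at 9899 and 15619 CPM.

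The other lists had medians from -0.05 to 0.48. Efferocytosis and scavenger receptors (18 measured, median 0.11) held Scarb1 at 0.92 and Mfge8 at -0.79, and Fc receptors (9 measured, 0.03) held Fcgr4 at 0.96. Inflammasome genes (15 measured, 0.07) held Nlrp3 at -2.19, eicosanoid synthesis (13 measured) also had a median of 0.07, and hypoxia response (14 measured) one of 0.11. Lysosomal genes lay at 0.07 (32 measured), apoptosis regulators at 0.04 (22 measured) with Mcl1 at -0.87, and p53 targets at 0.00 (12 measured) with Cdkn1a at -0.93. NRF2 and oxidative stress genes lay at 0.28 (23 measured), with the haem oxygenase gene Hmox1 at -0.81 and Gpx1 at 0.59. The medians of all these lists were below 0 under TMM scaling. Cytosolic ribosomal protein genes were at -0.03 (79 measured, -0.07 to 0.00) with 0 members 1.5-fold apart, and like the apoptosis and p53 lists lay below the central 95% of their random lists. The list of small and recruited macrophage genes (7 measured) was at -0.05 (-2.16 to 1.14), and its 3 members that are not class markers had a median of -1.62, with 0 above 0. G1/S genes lay at 0.48 (11 measured, -0.12 to 0.75), above the central 95% of their random lists, and G2/M genes at -0.01 (2 measured). The Y-linked genes Ddx3y and Eif2s3y were present at similar levels in both libraries (52.8 and 52.9 CPM, 41.2 and 46.5 CPM), and the 4 measured sex-linked genes had a median of 0.19, below 0 under TMM. Of the 40 lists, 5 had medians above and 15 below the central 95% of their random lists.

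Spp1 and Chil3 had the highest ratios in small-macrophage-like cells too. Spp1 was at 130 CPM in the knockout (cluster 6) and 0.608 CPM in the wild type library (cluster 5, from 10 UMIs), a log2 ratio of 6.35 (5.95 to 6.67). The wild type value lies below the 1 CPM added to each side, so the size of this ratio depends on that addition. Chil3 was at 1228 and 39.1 CPM (4.94, 4.83 to 5.05). The actin-binding protein gene Coro1a (2.51) and Car6 (2.06) followed, and Ccr2 (2.44) is a marker of the class. On the lower side were Ptgs2 (0.678 and 60.4 CPM, -5.19, -5.62 to -4.63), Tnfaip3 (-4.42), the chemokine gene Ccl7 (-4.39), Ccrl2 (-4.38) and Cxcl2 (-4.38). The knockout value of Ptgs2, from 6 UMIs, also lies below the added 1 CPM. The anti-inflammatory cytokine gene Il10 was at 0.226 and 43.3 CPM. Of 22 inflammatory genes 17 were at least 1.5-fold lower and 0 higher (median -2.22, -3.98 to -1.68), and of 22 immediate early genes 16 were lower and 0 higher (median -1.08, -1.93 to -0.49). Complement genes had a median of -0.54, mitochondrially encoded transcripts 0.76 and G1/S genes 0.99 (16 measured, 0.41 to 1.44), against 0.24 for the median gene of this class. The MHC class II genes that are not markers had a median of 0.32 here (5 measured, 4 above 0), near that value, and type I interferon (0.18) and interferon gamma response genes (0.29) lay inside the range of their random lists. Lists that hold naming genes differed as well: the small and recruited macrophage list was at 1.19, the whole MHC class II list at 0.86 and the resident large macrophage programme at -0.16. Clusters 6 and 5 may therefore hold different kinds of cell. Large macrophage markers were present in this class after thinning, Gata6 in 18.7% of knockout and 18.1% of wild type cells and Prg4 in 94.1% and 99.0%. In large-macrophage-like cells Gata6 was seen in 29.4% and 26.9%, and in B-cell-like barcodes in 0 of 33 and 0 of 37. Free RNA reaches Prg4, seen in 39.4% and 35.1% of B-cell-like barcodes. The class name rests on its naming markers alone. Past the 2-fold rule were 137 genes higher and 137 lower in the knockout library. Of 4900 genes at the floor in both classes, 80 were higher in large and 99 in small-macrophage-like cells, and 62 were shared where independent lists would share 1.62. Of the lower genes, 93 and 119, 85 were shared against 2.26, and 0 genes went in opposite directions. Both comparisons used separate cells of the same 2 libraries, so the lists are not independent. Part or all of this overlap may come from the libraries.

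Cycling cells (clusters 7 and 8 in the knockout, 8 and 12 in the wild type library) had Spp1 at 487 and 3.27 CPM (log2 ratio 6.84, 6.39 to 7.30), Chil3 at 4.06, Arg1 at 2.59, Rhoc at 2.08 and Kcnq1ot1 at 2.01. Tnfaip3 (-4.81), Ccrl2 (-3.76), Cxcl2 (624 and 6812 CPM, -3.45), Cxcl1 (-3.41) and Cxcl13 (-2.78) were lowest. Inflammatory genes had a median of -2.02 (21 measured, -2.57 to -0.77). Immediate early genes had one of -0.79 (19 measured, -1.14 to 0.07, an interval that crosses 0). Mitochondrially encoded transcripts lay at 1.27 (13 measured, 1.01 to 1.63) and type I interferon genes at 0.44 (21 measured, 0.19 to 0.69), against 0.14 for the median gene. The class differed in its make-up too, with medians of -0.95 for G2/M genes (26 measured, 0 above 0), -1.97 for the small and recruited macrophage list (9 measured) and -0.88 for MHC class II genes (8 measured, 0 above 0). The rule counted 111 genes as higher and 154 as lower. Over all cells, G1/S transcripts summed to 464 CPM in the knockout and 319 CPM in the wild type library, and G2/M transcripts to 389 and 512 CPM.

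**Figure D4:**
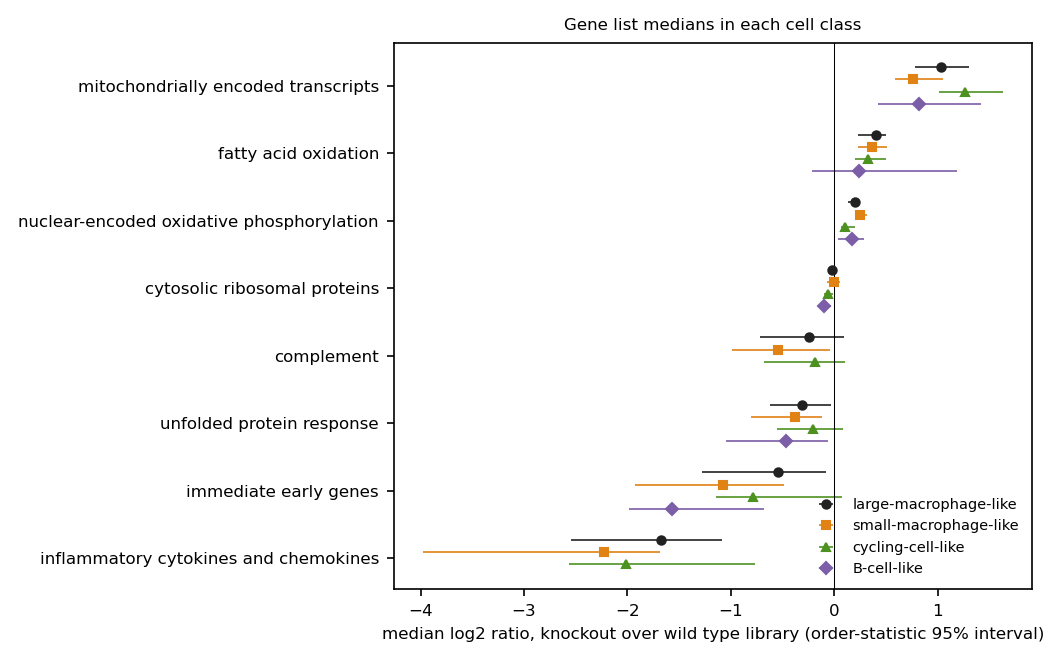
Median log2 ratio, knockout over wild type library, of 8 gene lists (y axis) in large-macrophage-like, small-macrophage-like, cycling-cell-like and B-cell-like cells (x axis, symbols), with order-statistic 95% intervals. Inflammatory genes lie at -1.68, -2.22 and -2.02 in the macrophage and cycling classes (not drawn, like complement, for B-cell-like cells, where free macrophage RNA can carry them) and mitochondrially encoded transcripts at 1.03, 0.76, 1.27 and 0.82 in these classes; oxidative phosphorylation in large-macrophage-like cells, at 0.20, lies below 0 under TMM scaling (-0.09).

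Some markers of other cell types were abundant in the large-macrophage-like cells of both libraries and others were near absent. The platelet marker Pf4 was at 3338 and 9307 CPM, the monocyte marker Hp at 151 and 110 CPM and the neutrophil marker Csf3r at 59.6 and 73.7 CPM, and Chil3 is a monocyte marker too. The neutrophil marker S100a9 was at 0.0490 CPM in the knockout and had 0 UMIs in the wild type library, S100a8 was at 25.9 CPM in the knockout library, and the monocyte marker Ly6c2 had 1 and 0 UMIs. Haemoglobin transcripts differed, with Hbb-bs at 65.7 and 24.3 CPM and Hba-a1 at 18.2 and 7.57 CPM. The monocyte marker Vcan was at 15.2 and 4.85 CPM. The B cell marker Cd79a was at 3.20 and 1.94 CPM, and the mast cell marker Cma1 had 0 and 61 UMIs.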

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

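The test on barcodes with many mitochondrial UMIs was chosen only after the result was seen. The cell filters left out 346 knockout barcodes (5.16%, 4.64 to 5.72%) and 56 wild type barcodes (0.887%, 0.671 to 1.15%); they are no part of the reported values, and some of them entered the settings with a minimum of 200 genes or no mitochondrial limit. Of these, 269 and 47 had under 500 genes and 269 and 23 had over 10% mitochondrial UMIs. Why more knockout barcodes lay outside the filters was not tested.

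Mitochondrially encoded transcripts and the nuclear RNAs Malat1, Neat1 and Kcnq1ot1 were higher in knockout large-macrophage-like cells. In small-macrophage-like cells Malat1, Neat1 and Kcnq1ot1 were at log2 ratios of 1.25, 1.14 and 1.82, all looked up after their values in large macrophages were seen. In B-cell-like barcodes Malat1 was at 1.40 (from 4886 and 2380 UMIs), Neat1 at 2.24 (19 and 5 UMIs, so 0.81 to 3.90) and Kcnq1ot1 at 1.53 (34 and 15 UMIs, lower bound 0.62); no wider set of nuclear RNAs was measured. A tail of cells above 5% mitochondrial UMIs did not carry the difference, as the large-macrophage-like median of mitochondrially encoded transcripts was 1.04 without them. Few cells were removed by that limit: 5999 knockout and 5932 wild type cells stayed, against 6036 and 5946 in the reported setting. Damage spread over most cells was therefore not tested. In B-cell-like barcodes the median of mitochondrially encoded transcripts was 0.82 (0.42 to 1.42). A property of the library that reached every cell type therefore stays open. An effect of the genotype in all cell types stays open too, untested.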

How the results depend on the processing

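Alternatives were chosen before the data were examined, except clustering on genes centred and scaled within each library, which was added after seeing the data. No paired analysis was possible because each genotype had 1 library and the labels link no pair. TMM scaling gave 42 genes higher and 162 lower in the knockout library and median of ratios 42 and 160, against 92 and 96; without a filter on low counts there were 374 and 157, and at 100 CPM or more 34 and 48. Other settings gave 71 to 104 higher and 84 to 108 lower genes. List medians above 0 numbered 24, and 6 under TMM and 6 under median of ratios. Among lists whose interval lay above 0, medians that went below 0 were, under TMM, autophagy (-0.0817), tricarboxylic acid cycle (-0.0586), nuclear-encoded oxidative phosphorylation (-0.0926), cholesterol synthesis (-0.0187) and actin, adhesion and migration (-0.0176), and under median of ratios -0.0753, -0.0521, -0.0861, -0.0132 and -0.0112. A list value counted as the same inside the interval of its reported median, and as reversed only where that interval excluded 0 and the sign changed. By this rule, of 480 list values 445 stayed the same, 25 moved and 10 reversed. Sign alone was kept by 22 of 40 medians under TMM and by 22 of 40 under median of ratios. Of 192 named gene values, set against their counting intervals, 67 stayed the same, 125 moved (35 up, 90 down) and 0 reversed. The named genes were picked for the most extreme ratios in these data, so the lack of reversals says little. The inflammatory median ran from -1.96 to -1.53 and that of mitochondrially encoded transcripts from 0.74 to 1.10. Shares of large-macrophage-like cells in the knockout and wild type libraries, then of small-macrophage-like cells, were 64.4% and 81.9%, 6.58% and 9.23% with a minimum of 200 genes (19.9% and 2.13% unnamed). They were 82.9% and 80.8%, 7.83% and 12.4% at no more than 5% mitochondrial UMIs, and 88.7% and 84.9%, 7.55% and 9.46% without that limit. With doublets kept they were 84.9% and 81.9%, 6.62% and 11.6%. Resolution 0.5 gave 85.7% and 86.2%, 6.11% and 7.32%, and resolution 2.0 gave 81.7% and 83.4%, 9.63% and 10.01%. Clustering each library alone gave 75.1% and 75.2%, 8.35% and 6.46%. Leaving 100 genes out of clustering gave 84.5% and 42.2%, 6.84% and 14.9% (36.5% of wild type cells unnamed). Thinning gave 84.3% and 68.2%, 7.07% and 25.2%, and centring within libraries 89.3% and 85.1%, 7.77% and 10.1%. The share of small-macrophage-like cells was higher in the wild type library in 9 of these 10 settings and that of large-macrophage-like cells higher in the knockout library in 6, so neither order is fixed.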

Other observations

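Of the tests in this part, the comparison of B-cell-like with macrophage levels, other than for Spp1 and Chil3, was chosen only after the result was seen. Early-response genes were lower in knockout B-cell-like barcodes too, by amounts that differed from those in macrophages. Fos, a transcription factor gene of the immediate early response, was at a log2 ratio of -2.33 in B-cell-like cells, with a smaller difference in large-macrophage-like cells (1065 and 1507 CPM). Its partner gene Jun was at -1.55 in B-cell-like cells and at 257 and 298 CPM in large-macrophage-like cells. The heat shock median was -1.38 in B-cell-like cells, with an interval across 0 (-1.61 to 0.54), and -0.15 in large-macrophage-like cells. Markers of large macrophages stood in B-cell-like barcodes at a median of 3.68% (knockout) and 3.31% (wild type) of their large-macrophage-like CPM, the level of free RNA. Inflammatory genes were there at 3.56% and 5.11%, so they say nothing about B cells, whereas immediate early genes were at 41.3% and 105%.

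Early-response list medians were lower in all 4 knockout classes and chemokine list medians in the 3 read for them. The early-response interval of cycling cells crossed 0 (-1.14 to 0.07). In B-cell-like cells the immediate early list stood at -1.57 (-1.99 to -0.68). Handling that differed between the libraries may therefore account for part or all of the early-response difference. An effect of the genotype in every cell type was not tested. The inflammatory median was -1.73 after thinning. Ratios of sums scaled to CPM can hardly change when cells are thinned at random, so this value does not decide on depth. The values argue against scaling set by a few abundant genes, as TMM shifted all ratios by -0.29, away from 0 for this list, to a median of -1.96.

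Spp1 and Chil3 were the genes with the highest ratios. Neutrophils are an unlikely source of Chil3, because S100a8 was at 25.9 CPM beside 350 CPM of Chil3. S100a8 was listed as a neutrophil marker, so it does not decide on monocytes. Of the monocyte markers, Ly6c2 had 1 and 0 UMIs in knockout and wild type large-macrophage-like cells. Vcan was at 15.2 and 4.85 CPM and Hp at 151 and 110 CPM, so a monocyte origin stays open. Free RNA falls short too, since knockout B-cell-like barcodes held Spp1 at 22.3 CPM (6.09 to 57.2, from 4 UMIs) against 632 CPM, and Chil3 at 33.5 CPM (12.3 to 73.0, from 6 UMIs) against 350 CPM. These genes could differ through Ankrd22, through a difference between the mice or through the capture, and these stay open. Ankrd22 had 0 UMIs in the wild type library too, so no loss of its transcript was seen in these cells.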
